A study of Apostichopus japonicus with 12 samples.

How the data were processed

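RNA from the intestine of the sea cucumber Apostichopus japonicus was sequenced in 12 libraries, with 3 libraries in each of 4 groups. Per the labels, the groups were a control at 18 °C, a high temperature group at 26 °C and 7 mg/L dissolved oxygen, a low oxygen group at 18 °C and 3 mg/L, and a combined group at 26 °C and 3 mg/L, each after 6 h of treatment. The series text gives 3 mg/L for the control as well, which is the level of the low oxygen group, so the oxygen level of the control was left unset and the groups were used as labelled. Per the labels' protocols, RNA was extracted from each animal, mRNA was purified, cDNA was primed with random hexamers, and libraries were sequenced on an Illumina HiSeq platform. No step that marks the strand is named there, so genes that overlap on opposite strands cannot be told apart. The labels do not say whether the 3 animals of a group came from separate tanks, and every p-value therefore measures the spread between these samples.

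The deposited table holds FPKM (fragments scaled by the length of the model in kilobases and by library size) for 26461 gene models, per the file headers, with names from Swiss-Prot matches and Pfam domains. Of these models, 19828 are predicted genes that also stand in the deposited annotation, and 6633 are added models that the table places outside it, called assembled models here. A Swiss-Prot match was given for 12030 models and a gene symbol for 11558, while 11886 had neither a match nor a domain. Gene names are those of the best match in another species. The aligner, the counting tool and the genome build are not given in the sources used here, and coordinates are those of the table, counted from 1. Exon numbers came from the deposited annotation. How reads of near-identical gene copies were counted is also not given in the sources used here, so members of multigene families, such as the HSP70, small heat shock, ribosomal and retroelement models, are uncertain as single genes. A reference table of symbols for this species could not be linked to the model names and was not used here.

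Multiplying each FPKM by the model's length gave whole multiples of a step per library for 100.0% of values, within 1e-06 of a fragment. Whole fragments could thus be recovered. The library size in that step equalled a median-of-ratios size factor over 12900 genes times the geometric mean of the library totals, with a largest relative difference of 2.6e-14. The deposited FPKM had therefore already been scaled between libraries by the authors in this way, although no header or label records it. Recovered fragments per library ranged from 8.147 to 10.855 in units of 1e6.

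All computing from there on was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. Genes with FPKM of at least 1 in at least 3 libraries were kept, which left 15615, and values were analysed as log2(FPKM + 1). A limma model with a mean per group was fitted to all 12 libraries (lmFit, contrasts.fit, eBayes with a trend in the variance), and 7 contrasts were tested, both sides. These were each treated group against control, the 3 comparisons among treated groups, and the interaction, defined as the combined minus low oxygen difference less the high temperature minus control difference. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and genes with an adjusted p under 0.05 were counted as changed. Every adjusted p of a single gene is from this limma model. With 3 libraries against 3, an exact permutation test of a single gene cannot go below 0.1.

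Gene lists were fixed before the data were examined: 31 lists of pathways and cell type markers, defined by patterns in symbols and descriptions, of which 29 had at least 5 tested members. They were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists of a contrast. Camera with a correlation estimated per list and fry were run beside it. Some list patterns caught strays: neurotrypsin models stand in the digestive enzyme list, carbohydrate sulfotransferases in the list of conjugation enzymes, and DDX helicases and major yolk protein in the germ line list. The HSP90 co-chaperone Cdc37 stands in the HSP90 list and, as a stray, in that of DNA replication and cell cycle. The small heat shock list had 4 tested members and the list of heat shock transcription factors 1, so neither was tested as a list.

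Named genes followed a rule fixed before the data were examined. For each comparison with control the rule took the 10 largest positive and 10 largest negative fold changes among named genes past the threshold whose libraries did not overlap between groups. For the other contrasts it took 5 and 5. To these were added up to 4 members with the smallest adjusted p of each list described, and, as sentinels, the most abundant HSP70, HSP90, hypoxia-inducible factor and lactate dehydrogenase genes. Genes named outside this rule are marked as chosen after their values were seen.

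The fit was tested on simulated data before use. For combined against control, with 15615 genes, it recovered 1.49% of genes shifted by log2 1, 32.2% of those shifted by log2 2 and 95.95% of those shifted by log2 4, with 6 false calls among 97. Most single changes of log2 1 or 2 were thus missed in the simulation, which real libraries may not match. To judge correlations between comparisons that share controls, unchanged groups with shared controls were simulated 100 times.

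Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter on low values and a filter at FPKM 5, values rescaled to equal totals per library, median-of-ratios factors, quantile normalization, a fit on the contrast's groups only, the replicate number as a block, eBayes without trend, robust eBayes, library weights (arrayWeights, with statmod 1.5.0), an added log2 threshold of 1, and leaving out each library in turn. Added after seeing the data were limma voom on the recovered fragments and a fit without both combined replicates 1 and 3. No deposited per-sample column was left out.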

Results

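The data describe gene expression in the intestine of the sea cucumber Apostichopus japonicus after 6 h in warm water, in water low in oxygen, or in both, each against a control at 18 °C. There were 3 libraries per group in 4 groups, and recovered depth ran from 8.147 (control 1) to 10.855 (low oxygen 3) in units of 1e6 fragments. The 10 most abundant models took from 19.8% of fragments in control 3 to 44.0% in combined 1. Combined 1 and combined 3 stood apart in this respect: their effective library sizes, which set the FPKM scale, were 0.529 and 0.526 of their totals, against 0.935 to 1.58 in the other libraries. The oxygen level of the control is in doubt, since the series text states 3 mg/L for it, so the comparisons with control and the interaction follow the group labels.

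Libraries within a group correlated at 0.755 to 0.855 in the control, 0.812 to 0.838 at high temperature, 0.832 to 0.872 at low oxygen and 0.735 to 0.792 in the combined group (Pearson r across genes, which are not independent replicates). Pairs of libraries from different groups ranged from 0.572 to 0.863, so groups overlapped in overall similarity.

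The comparison of high temperature with control asks what warming alone did. The 6 named genes that rose belong to the endoplasmic reticulum (ER) or the HSP90 system, and each was higher in all 3 warmed libraries than in any control library. Calumenin-B, a calcium-binding protein of the secretory pathway, rose from 12.8 ± 2.71 to 295 ± 50.4 FPKM (SD, n = 3 per group), a log2 fold change of 4.43 (SE 0.57, adjusted p = 0.0125). HSP90-beta, a cytosolic chaperone, rose from 67.1 ± 15.4 to 1343 ± 963 FPKM (log2 4.11, SE 0.54, adjusted p = 0.0125). AHSA1, which activates the HSP90 ATPase, rose by log2 3.95 (SE 0.52) to 84.4 ± 24.9 FPKM. In the ER, the protein disulfide isomerase PDIA4 rose by log2 3.19 (SE 0.42), endoplasmin, the HSP90 of the ER, by 2.82 (SE 0.40), and calreticulin, a lectin chaperone, by 2.62 (SE 0.32, from 60.3 ± 8.95 to 377 ± 68.0 FPKM).

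Calumenin-B (evm_TU_Chr14_573) lies on chromosome 14 from 26646582 to 26662246 in 6 exons. HSP90-beta (evm_TU_Chr2_1347) lies on chromosome 2 from 41433949 to 41444906 in 13 exons, and calreticulin (evm_TU_Chr7_293) on chromosome 7 from 9880128 to 9889205 in 9 exons. The genome build of these positions is not given in the sources used here.

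Of the 29 ER unfolded protein response genes tested, 3 rose over all genes and 11 rose adjusted over the list alone, with 26 positive and a list median of log2 1.12 (camera adjusted p = 4.48e-17, adjusted p = 0.0768 with an estimated correlation). BiP, the main HSP70 of the ER, measured 69.5 ± 9.04 FPKM in the control and 595 ± 89.9 at high temperature, which missed the threshold over all genes (log2 3.08, SE 0.57, adjusted p = 0.0788). The HSP90 list counted 2 of 12 over all genes and 5 adjusted over the list alone (camera adjusted p = 5.12e-09, adjusted p = 0.0768 with an estimated correlation). No HSP70 or HSP110 gene of 13 passed over all genes and 6 rose adjusted over the list alone (median log2 1.29, camera adjusted p = 6.78e-08, adjusted p = 0.0579 with an estimated correlation). In this list, an HSP70 IV gene measured 1.35 ± 1.04 FPKM in the control and 203 ± 245 in warm water, with single libraries at 25.9, 482 and 100.1 FPKM (adjusted p = 0.0788). Chaperonins, which fold proteins in the cytosol and mitochondria, counted 0 of 12 over all genes and 6 adjusted over the list alone (median log2 1.33, camera adjusted p = 1.41e-08, adjusted p = 0.0911 with an estimated correlation). HSP60 in that list measured 53.8 ± 15.9 FPKM in the control and 244 ± 148 at high temperature.

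Lipid metabolism genes were lower as a list, with a median of log2 -0.46 over 71 genes and 0 past the threshold over all genes, but 9 that fell adjusted over the list alone (camera adjusted p = 3.05e-09, adjusted p = 0.242 with an estimated correlation). Fatty acid synthase measured 198 ± 157 FPKM in the control and 1.40 ± 0.304 in warm water (log2 -5.70, adjusted p = 0.0694). Peroxisomal carnitine O-octanoyltransferase, which handles medium-chain acyl groups, measured 165 ± 127 and 0.545 ± 0.748 FPKM (adjusted p = 0.06). The fatty acid elongase ELOVL6 measured 74.7 ± 69.5 and 0.783 ± 1.36 FPKM (adjusted p = 0.0908), and ATP-citrate synthase, which supplies cytosolic acetyl-CoA, 86.6 ± 58.4 and 11.5 ± 1.38 FPKM (adjusted p = 0.0788). Control libraries differed widely in these genes, with fatty acid synthase at 22.8, 327 and 244 FPKM. Of the 4 models that fell over all genes, all assembled models without a name, 2 lie beside genes of fatty acid synthesis on the opposite strand, from which unstranded reads cannot be told apart. The model beside fatty acid synthase (chromosome 13, 1553338 to 1554511) fell by 6.60 on the log2 scale (SE 0.99, adjusted p = 0.0284), from 179 ± 88.9 to 1.04 ± 1.496 FPKM. The model beside ELOVL6 (chromosome 8, 3374740 to 3377448) fell by 3.86 (SE 0.51, adjusted p = 0.0125), and both were chosen after their values were seen.

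**Figure D1:**
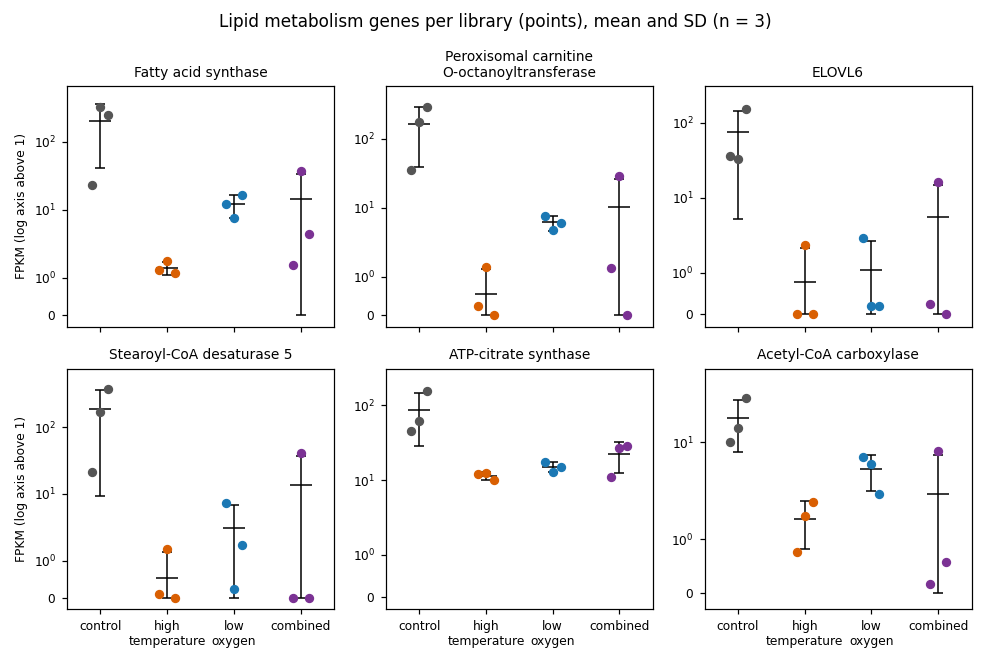
Lipid metabolism genes in each library. Points are FPKM of single libraries on an axis that is logarithmic above 1 and linear below, and bars are means with SD of 3 libraries whose lower end stops at 0. Fatty acid synthase ranged from 22.8 to 327 FPKM in the control libraries and from 1.17 to 1.74 at high temperature.

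Immediate early and stress transcription factors were higher as a list (15 genes, median log2 0.76, 0 past the threshold either over all genes or adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.0714 with an estimated correlation). Digestive enzymes were lower (66 genes, median log2 -0.38, 0 past the threshold either way, camera adjusted p = 0.00223, adjusted p = 0.242 with an estimated correlation). The digestive call ended with the filter at FPKM 5 (0.0599). Carboxypeptidase A1 measured 108 ± 175 FPKM in the control and 0.384 ± 0.554 in warm water. Glycolysis genes were lower (24 genes, median log2 -0.27, 0 past the threshold either way, camera adjusted p = 0.0275, adjusted p = 0.457 with an estimated correlation). The glycolysis call ended with library weights (0.465), a fit on these groups alone (0.0516), and without control 1 (0.0541), control 3 (0.292) or high temperature 3 (0.227). Markers of ciliated cells moved with the group: the cilia and flagella list had a median of log2 0.58 with 77 of 86 genes positive and 0 past the threshold either way (camera adjusted p = 1.48e-10, adjusted p = 0.475 with an estimated correlation).

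Over all 15615 genes, 7 rose and 4 fell at high temperature (limma), against 1027 with an unadjusted p under 0.05 where 781 would be expected by chance. In 14.1% of genes the 3 warmed and 3 control libraries did not overlap, where chance gives 10%. Without control 1, 7 genes rose and 9 fell. Without any other library of these groups 0 rose, so the named rises lost their call. Falls were then 2 (control 2), 1 (control 3, high temperature 2) or else 0. Weighting libraries by their spread gave 71 that rose and 134 that fell.

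The comparison of low oxygen with control asks what low oxygen did at 18 °C. A single gene passed the threshold, an unnamed assembled model on chromosome 2 (42195405 to 42198379) that fell by 4.06 on the log2 scale (SE 0.50, adjusted p = 0.0438) from 18.7 ± 11.6 to 0.0542 ± 0.0535 FPKM. It also fell at high temperature, and it was chosen after its values were seen. Neither hypoxia-inducible factor 1-alpha, the transcription factor that responds to low oxygen, nor lactate dehydrogenase A passed. The former measured 115 ± 51.7 FPKM in the control and 183 ± 122 at low oxygen (log2 0.58, SE 0.52, adjusted p = 0.862), and the latter 19.8 ± 10.1 and 19.1 ± 5.98 FPKM. The HIF pathway list of 10 genes had a median of log2 0.48 with 0 genes past the threshold (camera adjusted p = 0.131), and the glycolysis list a median of log2 -0.15 (camera adjusted p = 0.31).

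Several lists differed from other genes in this comparison, none of them with a gene past the threshold over all genes. Cytosolic ribosomal proteins were lower, with a median of log2 -0.64 and 79 of 80 negative, and 0 passed adjusted over the list alone (camera adjusted p = 4.92e-10, adjusted p = 0.583 with an estimated correlation). Oxidative phosphorylation genes were lower (72 genes, median log2 -0.44, 0 adjusted over the list alone, camera adjusted p = 4.81e-07, adjusted p = 0.536 with an estimated correlation). The complex I subunit NDUFB2 measured 67.01 ± 24.7 and 14.6 ± 11.8 FPKM. Mitochondrial ribosomal proteins were lower (67 genes, median log2 -0.49, 0 adjusted over the list alone, camera adjusted p = 8.01e-06, adjusted p = 0.536 with an estimated correlation). Lipid metabolism genes were lower (71 genes, median log2 -0.48, 5 that fell adjusted over the list alone, camera adjusted p = 7.35e-08, adjusted p = 0.536 with an estimated correlation). Stearoyl-CoA desaturase 5 measured 187 ± 178 and 3.06 ± 3.69 FPKM.

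Extracellular matrix genes, which serve here also as markers of connective tissue, were higher at low oxygen (63 genes, median log2 0.40, 46 positive, 2 that rose adjusted over the list alone, camera adjusted p = 0.000239, adjusted p = 0.536 with an estimated correlation). In that list SPARC, a collagen-binding matrix protein, measured 3.75 ± 1.60 FPKM in the control and 18.5 ± 5.74 at low oxygen (adjusted p = 0.194 over all genes). A TIMP3-like metalloproteinase inhibitor (evm_TU_Chr5_187) measured 15.0 ± 3.58 and 48.6 ± 6.25 FPKM (adjusted p = 0.406). Cilia and flagella genes were higher (median log2 0.32, 72 of 86 positive, 0 adjusted over the list alone, camera adjusted p = 0.00114, adjusted p = 0.678 with an estimated correlation). The cilia call ended with library weights (0.0787) and without control 3 (0.417). ER unfolded protein response genes were higher (median log2 0.42, 0 adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.583 with an estimated correlation). The ER call ended without control 1 (0.0801), low oxygen 1 (0.0712) or low oxygen 3 (0.0561). Tricarboxylic acid cycle genes were lower (32 genes, median log2 -0.28, 1 that fell adjusted over the list alone, camera adjusted p = 0.0363, adjusted p = 0.536 with an estimated correlation). That call ended when values were rescaled to equal totals (0.104), with library weights (0.0899) and without control 3 (0.475), low oxygen 1 (0.0593) or low oxygen 2 (0.0986).

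Over all genes, limma called 0 that rose and 1 that fell, with 984 at an unadjusted p under 0.05, and limma voom on recovered fragments called 0. The groups did not overlap in 16.2% of genes, where chance gives 10%. The count was 2 without control 1, 4 without control 2, and 0 without low oxygen 1 or low oxygen 3, and library weights gave 46 that rose and 139 that fell. The gene named above was called without control 2, but not without any other single library of these groups. It was also not called with either pseudocount, without a filter or with the filter at FPKM 5, with the replicate block, in a fit on these groups alone, with voom or when rescaled. Rescaling to equal totals put the median of all genes at log2 0.18 in this comparison.

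The comparison of the combined group with control asks what warming and low oxygen did together. The heat shock genes named next were higher by large factors in all 3 combined libraries than in any control library. An HSP70 IV gene (evm_TU_Chr2_501), a cytosolic chaperone of the stress-inducible kind by its name, rose from 0.794 ± 0.468 to 5153 ± 3415 FPKM (SD, n = 3 per group; log2 11.24, SE 1.10, adjusted p = 0.000265). A second HSP70 IV gene (evm_TU_Chr2_481) rose from 1.35 ± 1.04 to 6755 ± 6945 FPKM (log2 11.10, SE 1.04), and another on chromosome 10 (evm_TU_Chr10_597) from 1.79 ± 1.64 to 167 ± 82.9 FPKM (log2 5.93, SE 0.48). Small heat shock proteins, which hold unfolded proteins, rose as far: heat shock protein beta-1 from 0.493 ± 0.455 to 4307 ± 3638 FPKM (log2 11.07, SE 1.38) and alpha-crystallin A from 17.005 ± 24.9 to 11959 ± 9907 FPKM (log2 10.03, SE 1.43).

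These models lie on chromosome 2 (16541950 to 16546332, and 15987373 to 15991527), chromosome 10 (19802927 to 19809514) and chromosome 17 (15156465 to 15158310, and 15158840 to 15159796). The 3 HSP70 IV models have 2 exons each, and the 2 small heat shock models a single exon each. With limma voom on recovered fragments heat shock protein beta-1 was not called (adjusted p = 0.11). Their control values rest on few fragments: 97 for evm_TU_Chr2_501, 115 for evm_TU_Chr2_481 and 36 for heat shock protein beta-1 over the 3 control libraries. How reads of near-identical copies were shared among them is not given in the sources used here, so the share of each copy is uncertain.

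Of the 4 tested members of the small heat shock list 2 rose in the combined group, and the 1 tested heat shock transcription factor (hsf1, evm_TU_Chr9_130) did not pass (log2 -0.27, SE 0.37, adjusted p = 0.775). Of the 7 tested models with an HSP20 domain, 5 rose in the combined group (median log2 10.03), while 0 passed at high temperature (median log2 3.64) or at low oxygen (median log2 2.15). This set was chosen after its values were seen. Besides those named, these were 2 models matched to heat shock protein 67B3, up by log2 10.90 (SE 1.18) and 10.48 (SE 1.27), and Hsp-16.41, up by 7.09 (SE 1.03). Of these, heat shock protein 67B3 on chromosome 17 (adjusted p = 0.0644) and Hsp-16.41 (adjusted p = 0.121) were not called with limma voom on recovered fragments. Among HSP70 and HSP110 genes, 5 of 13 rose over all genes and 6 adjusted over the list alone (median log2 0.84, camera adjusted p = 2.13e-08), and this was the only list in any contrast to pass with an estimated correlation (adjusted p = 0.0457 with an estimated correlation). Its other called members were HSP110, up by log2 4.66 (SE 0.46), and BiP, up by log2 2.97 (SE 0.57, adjusted p = 0.0369).

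The HSP90 list counted 5 of 12 over all genes and 5 adjusted over the list alone (median log2 1.68, camera adjusted p = 2.13e-08, adjusted p = 0.121 with an estimated correlation). They were BAG3, a co-chaperone of HSP70 in the clearance of misfolded proteins (log2 6.84, SE 0.84), AHSA1 (4.84, SE 0.52), HSP90-beta (4.60, SE 0.54), STIP1, which links HSP70 to HSP90 (3.57, SE 0.66), and Cdc37 (2.82, SE 0.59). DnaJ genes, the HSP40 partners of HSP70, counted 3 of 35 over all genes and 6 adjusted over the list alone (median log2 0.19, camera adjusted p = 0.0109, adjusted p = 0.299 with an estimated correlation). Its list call ended when values were rescaled to equal totals (0.0617) and without combined 2 (0.108). DNAJB4 rose from 11.2 ± 5.30 to 1209 ± 490 FPKM (log2 6.65, SE 0.60, adjusted p = 0.000183), DNAJA1 by log2 3.90 (SE 0.63) and DNAJA2 by 2.55 (SE 0.46).

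Chaperonins counted 4 of 12 over all genes and 7 adjusted over the list alone (median log2 1.73, 12 positive, camera adjusted p = 1.39e-08, adjusted p = 0.121 with an estimated correlation). T-complex subunits gamma (log2 2.84, SE 0.51), delta (2.51, SE 0.42) and theta (1.90, SE 0.39) rose, as did mitochondrial HSP60 (2.65, SE 0.54). ER unfolded protein response genes counted 5 of 29 over all genes and 8 adjusted over the list alone (median log2 0.86, camera adjusted p = 8.06e-08, adjusted p = 0.299 with an estimated correlation). Calreticulin rose to 188 ± 16.1 FPKM (log2 1.63, SE 0.32, adjusted p = 0.038), endoplasmin by log2 2.10 (SE 0.40) and PDIA4 by 2.16 (SE 0.42). Of 21 alternatives these calls were kept in 11, 12 and 10, and that of BiP in 12. In combined 3 the ER list stood at log2 -0.06 above the control mean, against 1.16 and 1.24 in combined 1 and 2.

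**Figure D2:**
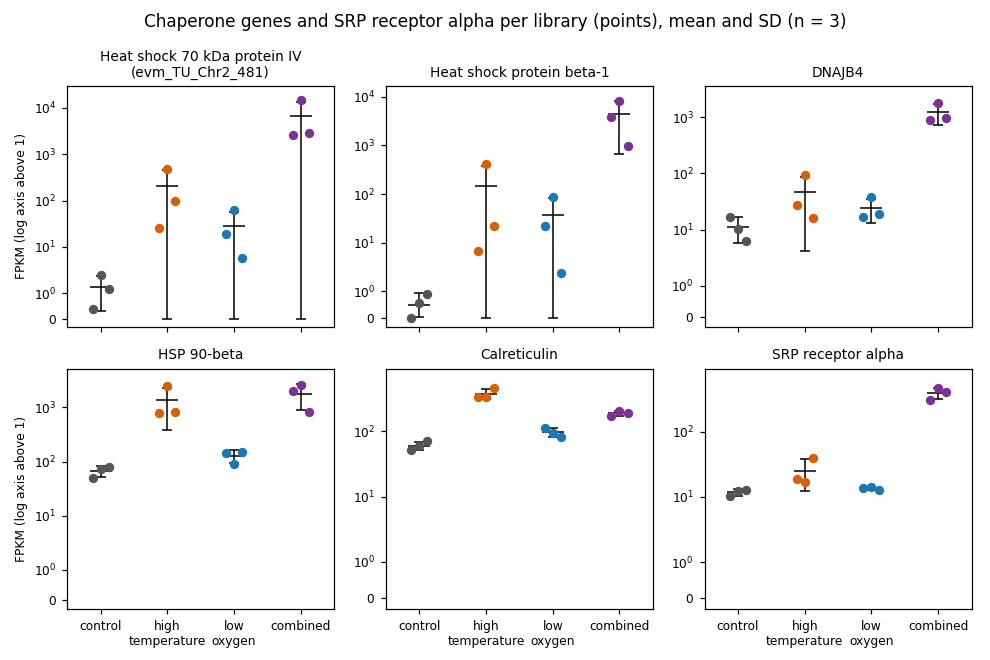
Chaperone genes and signal recognition particle receptor alpha in each library. Points are FPKM of single libraries on an axis that is logarithmic above 1 and linear below, and bars are means with SD of 3 libraries whose lower end stops at 0. DNAJB4 lay between 6.32 and 94.0 FPKM in the 9 libraries of the other groups and between 891 and 1773 in the combined group.

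Outside the chaperones, signal recognition particle receptor alpha, which guides ribosomes to the ER, also rose. It went from 11.8 ± 1.33 to 395 ± 81.4 FPKM (log2 4.93, SE 0.37, adjusted p = 4.1e-05). This model (evm_TU_Chr15_285) lies on chromosome 15 from 8964154 to 8980055 in 15 exons. Of the immediate early and stress transcription factors, 1 of 15 rose over all genes and 3 adjusted over the list alone (median log2 0.45, camera adjusted p = 0.0109, adjusted p = 0.121 with an estimated correlation). The called gene was C/EBP beta, from 150.2 ± 27.1 to 1148 ± 831 FPKM (log2 2.71, SE 0.45). That list's call ended under quantile normalization (0.0662) and without combined 2 (0.0865). The HIF pathway list had 0 of 10 over all genes and 2 that rose adjusted over the list alone (median log2 0.54, camera adjusted p = 0.0279, adjusted p = 0.321 with an estimated correlation). In it hypoxia-inducible factor 1-alpha measured 392 ± 159 FPKM (log2 1.79, SE 0.52, adjusted p = 0.171). The HIF call ended when values were rescaled to equal totals (0.0629), under quantile normalization (0.0662), and without combined 1 (0.21) or combined 2 (0.0652).

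The named genes with the largest falls in the combined group were of mixed kinds. A pair of hyalin fragments, named for an adhesion protein of the echinoderm embryo, fell by 5.01 (SE 1.01, evm_TU_Chr6_579) and 3.46 (SE 0.69, evm_TU_Chr6_578) on the log2 scale and lie beside each other on chromosome 6 (22522702 to 22527410, and 22515055 to 22519875). An autocrine proliferation repressor A match fell by 4.48 (SE 0.92), from 49.9 ± 62.9 to 0.219 ± 0.379 FPKM. A fibrinogen-like protein A model fell by 3.52 (SE 0.64), an armadillo-like helical protein by 3.36 (SE 0.65) and a model matched to the catalytic subunit A of the V-type proton pump by 2.66 (SE 0.46). Tartrate-resistant acid phosphatase type 5 fell by 2.49 (SE 0.47) and adhesion receptor B3 by 2.35 (SE 0.47). The 3 combined libraries lay below the 3 controls in every case, which the naming rule required. None of these falls was called with limma voom on recovered fragments or in a fit on these groups alone.

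Lipid metabolism genes were again lower as a list, with 0 of 71 past the threshold over all genes and 12 that fell adjusted over the list alone (median log2 -0.75, camera adjusted p = 1.12e-07, adjusted p = 0.299 with an estimated correlation). Acetyl-CoA carboxylase, the first step of fatty acid synthesis, measured 17.7 ± 9.79 FPKM in the control and 2.95 ± 4.48 in the combined group (log2 -2.75, adjusted p = 0.107). ELOVL6 measured 5.45 ± 9.22 FPKM in the combined group (log2 -4.39, adjusted p = 0.0797). Cytosolic ribosomal proteins were higher by a median of log2 0.86, with 76 of 80 positive and 0 past the threshold either over all genes or adjusted over the list alone (camera adjusted p = 4.57e-11, adjusted p = 0.518 with an estimated correlation). They were lower than other genes under quantile normalization (camera adjusted p = 0.0148). The median of this list above the control mean was 0.65, 0.08 and 1.88 in the 3 combined libraries. As a share of fragments the list took 6.02% and 7.08% in combined 1 and 2 and 13.025% in combined 3, against 7.99% to 9.02% in the controls. Rescaled to equal totals, the list kept its call against other genes (camera adjusted p = 2.02e-05), while its own median was log2 -0.020.

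Oxidative phosphorylation genes (72 genes, median log2 0.17, 0 past the threshold either way, camera adjusted p = 0.0456, adjusted p = 0.757 with an estimated correlation) were higher than other genes as deposited and lower when quantile normalized (0.0592). The call was lost when rescaled to equal totals (0.317), with the list median still log2 0.076 above that of all genes. It also ended with the filter at FPKM 5 (0.201), the replicate block (0.0587) and library weights (0.0548), and without control 1 (0.208), control 2 (0.182) or combined 3 (0.846). Ubiquitin and proteasome genes (83 genes, median log2 0.26, 1 that rose adjusted over the list alone and 0 over all genes, camera adjusted p = 0.0456, adjusted p = 0.364 with an estimated correlation) were likewise higher as deposited. Their call was lost when rescaled to equal totals (0.749, list median log2 0.23 above that of all genes) and under quantile normalization (0.564). It ended too with the filter at FPKM 5 (0.0739), a fit on these groups alone (0.0748), the replicate block (0.0626) and library weights (0.163), and without control 1 (0.177), combined 2 (0.108) or combined 3 (0.212).

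Markers of other cell types moved with the combined group. Extracellular matrix genes were higher (median log2 0.58, 50 of 63 positive, 1 that rose over all genes and 6 adjusted over the list alone, camera adjusted p = 3.43e-07, adjusted p = 0.125 with an estimated correlation). The called gene was SPARC, at 15.5 ± 3.56 FPKM (log2 1.84, SE 0.38, adjusted p = 0.0488). Cilia and flagella genes were higher (median log2 0.92, 80 of 86 positive, 0 past the threshold either way, camera adjusted p = 3.95e-12, adjusted p = 0.364 with an estimated correlation). The difference lay mostly in combined 1, where the list stood at 2.05 above the control mean against 0.10 and 0.50 in the other libraries. Muscle contractile genes (18 genes, median log2 0.55, 0 past the threshold either way, camera adjusted p = 0.00164, adjusted p = 0.305 with an estimated correlation) were higher. The muscle call ended when values were rescaled to equal totals (0.0503) or quantile normalized (0.13). Innate immune effectors (91 genes, median log2 0.55, 0 past the threshold either way, camera adjusted p = 0.0238, adjusted p = 0.3 with an estimated correlation) were higher. The immune call ended with the filter at FPKM 5 (0.355), with library weights (0.145) and without control 3 (0.105) or combined 3 (0.235).

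**Figure D3:**
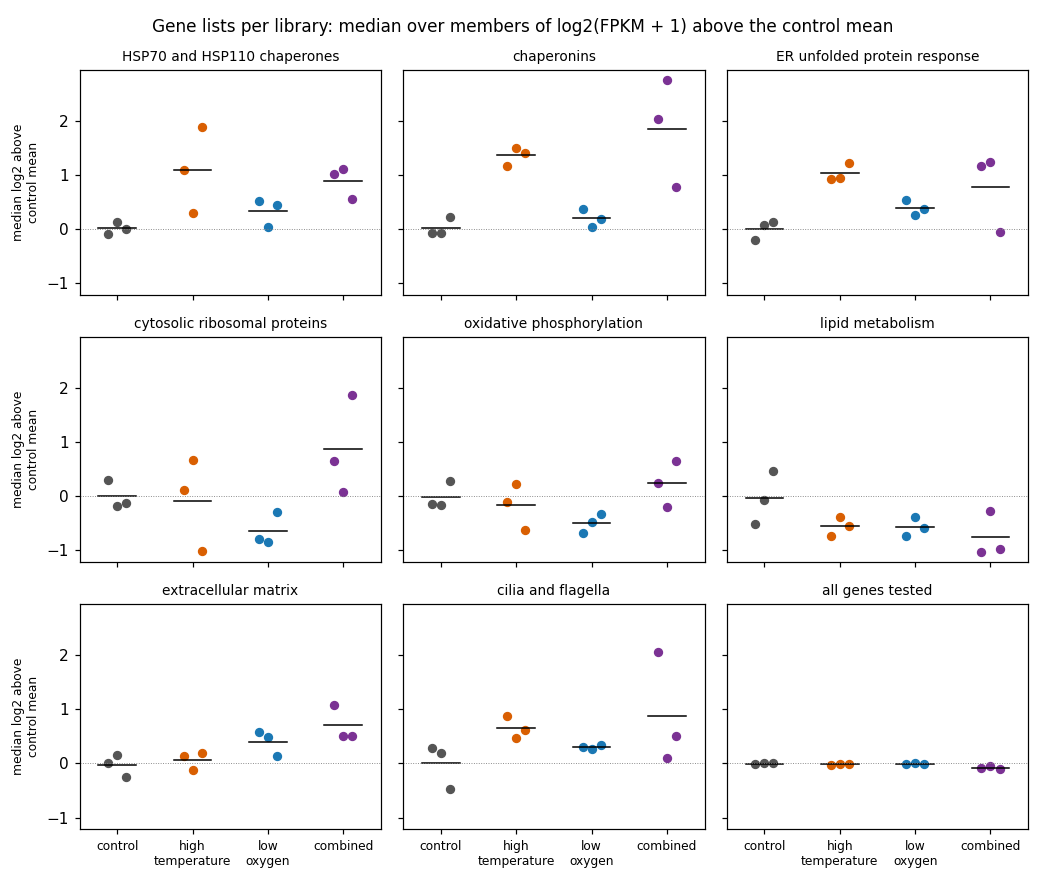
Gene lists in each library. Each point is the median over a list's members of log2(FPKM + 1) above the mean of the 3 control libraries, and black lines are group means. The cytosolic ribosomal protein list stood at 1.88 in combined 3 and at -1.01 in high temperature 3, and its position above other genes in the combined group turns under quantile normalization.

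Over all genes, 93 rose and 30 fell in the combined group, with 2148 at an unadjusted p under 0.05. Limma voom on recovered fragments called 57 that rose and 0 that fell, and a fit on these groups alone 30 and 0. With a pseudocount of 0.1 the falls numbered 6, without control 3 they numbered 8, and without combined 1, or without both combined replicates 1 and 3, they numbered 2. In 14.4% of genes the groups did not overlap, where chance gives 10%. Rising genes made up 75.6% of calls as deposited and 38.1% (37 rose, 60 fell) when values were rescaled to equal totals, which put the median of all genes at log2 -0.77. The count of changed genes was 72 without control 2, 51 without control 3, 50 without combined 1, 196 without combined 2 and 212 without combined 3, of which 60, 46, 48, 89 and 102 were among the genes called with all libraries.

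The contrast of the combined with the high temperature group asks what low oxygen added in warm water. Heat shock genes rose again: a heat shock protein 67B3 model (evm_TU_Chr17_459) from 21.8 ± 28.04 to 4631 ± 6002 FPKM (log2 7.56, SE 1.18, adjusted p = 0.0164), BAG3 by log2 5.21 (SE 0.84) and DNAJB4 by log2 4.99 (SE 0.60, adjusted p = 0.00265). HSP90-beta did not pass (log2 0.49, SE 0.54), nor did the HSP70 IV gene evm_TU_Chr2_481 (log2 5.46, SE 1.04, adjusted p = 0.0782). A Ty3-G retroelement match on chromosome 3 (7556301 to 7563087) rose by log2 4.50 (SE 0.58), from 0.172 ± 0.205 to 33.9 ± 31.1 FPKM. The WSCD family member CG9164 rose by log2 4.24 (SE 0.50), from 0.296 ± 0.456 to 27.2 ± 18.3 FPKM. A calcium-activated chloride channel regulator (evm_TU_Chr22_537) fell by 2.46 on the log2 scale (SE 0.42), from 15.1 ± 3.98 to 2.08 ± 1.44 FPKM.

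Against high temperature, HSP70 and HSP110 genes counted 1 of 13 over all genes (evm_TU_Chr10_597, log2 3.20, SE 0.48, adjusted p = 0.012) and 4 adjusted over the list alone (median log2 0.38, camera adjusted p = 0.00147, adjusted p = 0.288 with an estimated correlation). The HSP70 call ended under quantile normalization (0.0581) and without combined 2 (0.0865). Extracellular matrix genes were higher (median log2 0.57, 0 past the threshold either way, camera adjusted p = 2.34e-07, adjusted p = 0.288 with an estimated correlation). Cytosolic ribosomal proteins were higher by a median of log2 0.95 (77 of 80 positive, 0 past the threshold either way, camera adjusted p = 4.73e-18, adjusted p = 0.732 with an estimated correlation) but lower than other genes under quantile normalization (0.0581). Muscle contractile genes were higher (median log2 0.79, 0 either way, camera adjusted p = 0.000308, adjusted p = 0.462 with an estimated correlation), which ended under quantile normalization (0.155). Innate immune effectors (median log2 0.37, 0 either way, camera adjusted p = 0.00477, adjusted p = 0.397 with an estimated correlation) lost their call with the filter at FPKM 5 (0.0949) and without high temperature 3 (0.0527) or combined 3 (0.129).

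The remaining lists past the threshold in this contrast each turned or ended under several settings. Oxidative phosphorylation genes were higher (median log2 0.39, 0 either way, camera adjusted p = 9.93e-05, adjusted p = 0.732 with an estimated correlation) and lower under quantile normalization (0.485). There was no call when rescaled to equal totals (0.78) or without high temperature 3 (0.129) or combined 3 (0.123). Chaperonins were higher (median log2 0.42, 0 either way, camera adjusted p = 0.0491, adjusted p = 0.732 with an estimated correlation) and lower under quantile normalization (0.846). The call was lost when rescaled to equal totals (0.384), with the filter at FPKM 5 (0.117), a fit on these groups alone (0.073), the replicate block (0.0573) and eBayes without trend (0.0509), and without high temperature 1 (0.265), high temperature 3 (0.0527), combined 1 (0.253) or combined 2 (0.739). RNA splicing factors were higher (median log2 0.17, 0 either way, camera adjusted p = 0.0442, adjusted p = 0.732 with an estimated correlation) and lower when quantile normalized (0.635). Rescaled to equal totals, their median stayed log2 0.081 above that of all genes, without a call (0.27). The filter at FPKM 5 (0.138), a fit on these groups alone (0.073), the replicate block (0.0569) and library weights (0.145) ended it too. Without high temperature 1 (0.184), high temperature 3 (0.0657), combined 2 (0.0792) or combined 3 (0.856) the splicing call was also lost. Cilia and flagella genes were higher (median log2 0.20, 0 either way, camera adjusted p = 0.0406, adjusted p = 0.875 with an estimated correlation) and lower than other genes without combined 1 (0.00103). The cilia call ended when rescaled to equal totals (0.225), with a pseudocount of 0.1 (0.0681), the filter at FPKM 5 (0.0707) and a fit on these groups alone (0.0573), and without high temperature 2 (0.436) or high temperature 3 (0.0586). ER unfolded protein response genes were lower (median log2 -0.26, 0 either way, camera adjusted p = 0.0442, adjusted p = 0.732 with an estimated correlation). This ended with a pseudocount of 0.1 (0.0681), a fit on these groups alone (0.073), the replicate block (0.0573), library weights (0.228) and without high temperature 3 (0.25), and turned without combined 3 (0.745).

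In all, 32 genes rose and 2 fell against high temperature, with 1038 at an unadjusted p under 0.05 and 9.5% of genes without overlap where chance gives 10%. Rescaled to equal totals, 12 rose and 5 fell, a fit on these groups alone gave 2, and the count was 22 without high temperature 3 and 67 without combined 3.

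The contrast of the combined with the low oxygen group asks what warming added in water low in oxygen. The HSP70 IV gene evm_TU_Chr2_481 rose from 28.8 ± 29.1 to 6755 ± 6945 FPKM (log2 7.88, SE 1.04, adjusted p = 0.00364). Further rises were in evm_TU_Chr2_501 by log2 7.59 (SE 1.10), both heat shock protein 67B3 models by log2 8.68 (SE 1.18) and 8.33 (SE 1.27), and alpha-crystallin A by log2 7.79 (SE 1.43). HSP90-beta rose from 127.1 ± 32.5 to 1797 ± 888 FPKM (log2 3.70, SE 0.54). Of the 4 genes that fell, 2 had a name. Monocarboxylate transporter 3, a carrier of lactate and pyruvate (evm_TU_Chr3_457), fell by 2.82 on the log2 scale (SE 0.45, adjusted p = 0.0164), from 102 ± 43.0 to 14.4 ± 8.50 FPKM, and the steroid reductase HSD17B7 fell by 1.91 (SE 0.34).

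Against low oxygen, HSP70 and HSP110 genes counted 4 of 13 over all genes and 6 adjusted over the list alone (median log2 0.98, camera adjusted p = 1.18e-06, adjusted p = 0.0966 with an estimated correlation). The HSP90 list counted 4 of 12 and 6 adjusted over the list alone (median log2 1.63, camera adjusted p = 4.14e-07, adjusted p = 0.184 with an estimated correlation). Chaperonins counted 3 of 12 and 8 adjusted over the list alone (median log2 1.58, camera adjusted p = 1.25e-08, adjusted p = 0.184 with an estimated correlation). DnaJ genes counted 1 of 35 and 4 adjusted over the list alone (camera adjusted p = 0.0044, adjusted p = 0.358 with an estimated correlation). The DnaJ call ended when rescaled to equal totals (0.0668) and without combined 2 (0.107). ER unfolded protein response genes counted 0 of 29 and 7 adjusted over the list alone (median log2 0.46, camera adjusted p = 0.000718, adjusted p = 0.508 with an estimated correlation). The ER call was lost when rescaled to equal totals (0.0809), when quantile normalized (0.0814) and without combined 2 (0.0997).

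Cytosolic ribosomal proteins were higher than at low oxygen by a median of log2 1.499, with 1 of 80 past the threshold over all genes and 69 adjusted over the list alone (camera adjusted p = 1.66e-30, adjusted p = 0.364 with an estimated correlation). The ribosomal list call was lost under quantile normalization (0.38). The called gene was RPS27L, from 107.5 ± 5.24 to 546 ± 210.1 FPKM (log2 2.26, SE 0.39, adjusted p = 0.0276). Oxidative phosphorylation genes counted 1 of 72 over all genes and 1 adjusted over the list alone (median log2 0.67, camera adjusted p = 3.59e-10, adjusted p = 0.364 with an estimated correlation). The called gene was NDUFB2, from 14.6 ± 11.8 to 208 ± 35.3 FPKM (log2 4.31, SE 0.81). Mitochondrial ribosomal proteins were higher (median log2 0.29, 0 either way, camera adjusted p = 0.00258, adjusted p = 0.508 with an estimated correlation), which ended when rescaled to equal totals (0.34) and without combined 3 (0.479).

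Muscle contractile genes were higher than at low oxygen (median log2 0.66, 6 that rose adjusted over the list alone and 0 over all genes, camera adjusted p = 0.000623, adjusted p = 0.364 with an estimated correlation), a call lost under quantile normalization (0.107). Cilia and flagella genes were higher (median log2 0.63, 0 either way, camera adjusted p = 7.16e-06, adjusted p = 0.63 with an estimated correlation), which ended without combined 1 (0.935). Extracellular matrix genes were higher (median log2 0.32, 2 adjusted over the list alone and 0 over all genes, camera adjusted p = 0.0496, adjusted p = 0.508 with an estimated correlation). The matrix call ended when rescaled to equal totals (0.29), under quantile normalization (0.833), with the filter at FPKM 5 (0.269), median-of-ratios factors (0.0502), eBayes without trend (0.0512) and library weights (0.0654), and without low oxygen 3 (0.345), combined 1 (0.229) or combined 2 (0.0997). ABC transporters were lower (48 genes, median log2 -0.33, 0 either way, camera adjusted p = 0.0299, adjusted p = 0.364 with an estimated correlation). The transporter call ended when rescaled to equal totals (0.0588), under quantile normalization (0.106) and without low oxygen 3 (0.0744), combined 1 (0.106) or combined 3 (0.069). Autophagy and lysosome genes were lower (43 genes, median log2 -0.36, 0 over all genes, camera adjusted p = 0.026, adjusted p = 0.283 with an estimated correlation), although the 1 member that passed adjusted over the list alone rose. The autophagy call ended with the filter at FPKM 5 (0.159) and without low oxygen 2 (0.0591), combined 2 (0.0678) or combined 3 (0.0521).

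In all, 62 genes rose and 4 fell against low oxygen, with 1931 at an unadjusted p under 0.05 and 15.6% of genes without overlap where chance gives 10%. Rising genes made up 93.9% of calls as deposited and 75% (21 rose, 7 fell) when rescaled to equal totals. The count was 34 without low oxygen 1, 38 without low oxygen 2, 38 without low oxygen 3, 37 without combined 1 and 113 without combined 3, and a fit on these groups alone gave 22.

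High temperature and low oxygen were also compared directly, which involves no control library. Calumenin-B alone passed (log2 4.56, SE 0.57, adjusted p = 0.0453), at 295 ± 50.4 FPKM in warm water and 11.9 ± 3.75 at low oxygen, and 770 genes had an unadjusted p under 0.05. Leaving out any single library of these groups ended that call. The ER list was higher in warm water (median log2 0.43, 0 of 29 over all genes and 10 adjusted over the list alone, camera adjusted p = 1.19e-10, adjusted p = 0.179 with an estimated correlation). Also higher were chaperonins (0 and 5, camera adjusted p = 1.73e-08, adjusted p = 0.135 with an estimated correlation), HSP90 genes (0 and 5, camera adjusted p = 2.82e-07, adjusted p = 0.135 with an estimated correlation) and HSP70 and HSP110 genes (0 and 4, camera adjusted p = 7.73e-05, adjusted p = 0.135 with an estimated correlation).

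Between the same groups, cytosolic ribosomal proteins (median log2 0.58, camera adjusted p = 1.33e-09, adjusted p = 0.565 with an estimated correlation) and mitochondrial ribosomal proteins (median log2 0.45, camera adjusted p = 1.31e-07, adjusted p = 0.235 with an estimated correlation) were higher in warm water, each with 0 members past the threshold either over all genes or adjusted over the list alone. Oxidative phosphorylation genes (median log2 0.25, 0 either way, camera adjusted p = 0.000247, adjusted p = 0.565 with an estimated correlation) were higher too, a call lost without high temperature 2 (0.0825). Extracellular matrix genes were lower in warm water (median log2 -0.30, camera adjusted p = 0.00177, adjusted p = 0.304 with an estimated correlation), with 0 past the threshold over all genes and 1 that rose and 1 that fell adjusted over the list alone. Autophagy and lysosome genes were lower (median log2 -0.38, 0 either way, camera adjusted p = 0.00177, adjusted p = 0.135 with an estimated correlation). DnaJ genes were higher (median log2 0.27, 0 over all genes and 3 adjusted over the list alone, camera adjusted p = 0.0301, adjusted p = 0.35 with an estimated correlation). The DnaJ call was lost when rescaled to equal totals (0.059), with the filter at FPKM 5 (0.0617) and without high temperature 2 (0.0825), high temperature 3 (0.0959), low oxygen 2 (0.0927) or low oxygen 3 (0.0636).

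Marker and transport lists also differed between warm water and low oxygen, each with 0 members past the threshold either over all genes or adjusted over the list alone. Cilia and flagella genes were higher in warm water (median log2 0.33, camera adjusted p = 0.00177, adjusted p = 0.696 with an estimated correlation), lost without high temperature 1 (0.117). ABC transporters were lower (median log2 -0.18, camera adjusted p = 0.00698, adjusted p = 0.235 with an estimated correlation), lost without the same library (0.117). Innate immune receptors were lower (33 genes, median log2 -0.34, camera adjusted p = 0.018, adjusted p = 0.235 with an estimated correlation), lost with the filter at FPKM 5 (0.112) and without high temperature 2 (0.0672). Germ line genes were lower (25 genes, median log2 -0.38, camera adjusted p = 0.0301, adjusted p = 0.293 with an estimated correlation), lost with the filter at FPKM 5 (0.0975), with library weights (0.111) and without high temperature 2 (0.352) or low oxygen 3 (0.334). Digestive enzymes were lower (median log2 -0.14, camera adjusted p = 0.0459, adjusted p = 0.38 with an estimated correlation), lost when rescaled to equal totals (0.0688), with the filter at FPKM 5 (0.0555), a fit on these groups alone (0.0968) and library weights (0.0618), and without high temperature 1 (0.18), high temperature 2 (0.0672), low oxygen 2 (0.0911) or low oxygen 3 (0.157).

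The interaction contrast asks whether the combined response departed from the sum of the single responses on the log scale. Signal recognition particle receptor alpha exceeded that sum by log2 3.82 (SE 0.53, adjusted p = 0.0181), with 11.8 ± 1.33 FPKM in the control, 25.2 ± 12.95 at high temperature, 13.5 ± 0.625 at low oxygen and 395 ± 81.4 in the combined group. A retrovirus-related Pol match, an assembled model on chromosome 4 (28877190 to 28883978), exceeded it by log2 4.06 (SE 0.53, adjusted p = 0.0181), with 0.298 ± 0.0406, 1.11 ± 0.973, 0.297 ± 0.299 and 31.3 ± 3.01 FPKM in the same order. The other 6 of the 8 genes that passed had no name, and 0 genes passed in the negative direction, with 1024 at an unadjusted p under 0.05. The count fell to 2 without control 2, high temperature 1 or any low oxygen library, was 3 without high temperature 3 and 5 without high temperature 2, and reached 13 without combined 2 and 18 without combined 3. Limma voom on recovered fragments called 0, and rescaling to equal totals left 1 that rose and 1 that fell, a rising share of 50% against 100% as deposited.

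Single heat shock genes did not pass the interaction: the HSP70 IV gene evm_TU_Chr2_481 had log2 2.24 (SE 1.47) and HSP90-beta log2 -0.41 (SE 0.76). Cytosolic ribosomal proteins had a median interaction of log2 1.64 with 79 of 80 positive (camera adjusted p = 2.42e-25, adjusted p = 0.713 with an estimated correlation), a call lost under quantile normalization (0.331). Oxidative phosphorylation genes had a median of log2 0.89 with 64 of 72 positive (camera adjusted p = 2.74e-10, adjusted p = 0.713 with an estimated correlation). The ER list had a median of log2 -0.65 with 5 of 29 positive (camera adjusted p = 0.00145, adjusted p = 0.713 with an estimated correlation), lost without combined 3 (0.0829), and calreticulin in it had log2 -1.65 (SE 0.45, adjusted p = 0.517). Lipid metabolism genes had a median of log2 0.47 (camera adjusted p = 0.00151, adjusted p = 0.713 with an estimated correlation), lost without control 3 (0.162) or combined 2 (0.228), with 2 that passed adjusted over the list alone, while 0 members of the lists in this paragraph passed over all genes.

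Muscle contractile genes had a median interaction of log2 0.62 (camera adjusted p = 0.00892, adjusted p = 0.713 with an estimated correlation), lost when rescaled to equal totals (0.103), under quantile normalization (0.389) and without control 1 (0.0614) or combined 1 (0.0529). Mitochondrial ribosomal proteins had a median of log2 0.46 (camera adjusted p = 0.0402, adjusted p = 0.713 with an estimated correlation). This was lost when rescaled to equal totals (0.685), with the filter at FPKM 5 (0.118), the replicate block (0.0517) and library weights (0.277), and without control 1 (0.0539), control 3 (0.162), high temperature 3 (0.209), low oxygen 2 (0.18) or combined 3 (0.707). RNA splicing factors had a median of log2 0.28 (camera adjusted p = 0.0434, adjusted p = 0.713 with an estimated correlation). Their call was lost when rescaled to equal totals (0.683, list median log2 0.15 above that of all genes), under quantile normalization (0.987), with the filter at FPKM 5 (0.148), the replicate block (0.0517) and library weights (0.168), and without 7 of the 12 libraries. No member of these 3 lists passed over all genes or adjusted over the list alone.

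Across the 3 comparisons with control, the lists of antioxidant and glutathione enzymes, apoptosis, DNA replication and cell cycle, cytochrome P450 and conjugation enzymes, and neuronal genes did not pass in any contrast. In the combined group their camera adjusted p was 0.509, 0.502, 0.89, 0.169 and 0.502. Within the P450 and conjugation list 2 sulfotransferases of the SULT1B1 kind fell, by 2.25 (SE 0.44) and 1.90 (SE 0.39) on the log2 scale.

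All 7 genes that rose and 3 of the 4 that fell at high temperature also did so in the combined group, where independent lists would share 0.0417 and 0.00769. The 3 controls cannot be split into groups large enough for a repeat, so these overlaps could not be separated from the shared control libraries. The log2 fold changes at high temperature and in the combined group correlated at r = 0.664 across genes (simulated median 0.481, range -0.60 to 0.934) with a covariance of 0.463 (simulated 0.196). For high temperature and low oxygen r was 0.646 (simulated 0.493) with a covariance of 0.342 (simulated 0.217) and 1 gene that fell in both. For low oxygen and combined r was 0.529 (simulated 0.522) with a covariance of 0.371 (simulated 0.225) and 1 gene that fell in both.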

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

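Among the tests of explanations in this part, those on full-length retroelements, on transcripts running on from nearby genes, on the chaperones' dependence on scaling and on scaling as the whole cause of the rise were chosen after the results were seen. A test of the difference itself, the interaction of temperature and oxygen, picked out 8 genes and 7 gene lists whose response to warming differed between the oxygen levels. The Pol match on chromosome 4 (log2 4.06) and signal recognition particle receptor alpha (log2 3.82) were the named genes. The lists had medians of log2 1.64 for cytosolic ribosomal proteins, 0.89 for oxidative phosphorylation, 0.62 for muscle contractile proteins, 0.47 for lipid metabolism, 0.46 for mitochondrial ribosomal proteins, 0.28 for RNA splicing factors and -0.65 for the ER unfolded protein response. None of these lists passed with an estimated correlation (adjusted p = 0.713 each), and camera put the splicing list in the other direction when values were rescaled to equal totals (0.683), with its median still log2 0.15 above that of all genes. Rescaled, muscle contractile (0.103) and mitochondrial ribosomal proteins (0.685) were not called either, while digestive enzymes were (0.00132). Groups of 3 libraries are too small for the test of single outlying samples. Of 100 arrangements of the libraries, the real one included, 4 gave as many interaction genes as the real 8. The highest other arrangement gave 24. A count of that size, several times the real one, points to a structure of the samples, whose nature was not tested. It includes the treatments, whose effects rearranged libraries carry, so these counts cannot exclude chance.

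The combined group had more changed genes (93 up and 30 down) than high temperature (7 up and 4 down) or low oxygen (1 down). The scaling between libraries could carry part of this, since 2 combined libraries had effective sizes of 0.529 and 0.526 of their totals. Leaving out a single combined library gave at least 50 changed genes, against the count resting on 1 library, and when rescaled to equal totals 37 of the 93 rising genes kept an adjusted p under 0.05. The median of the 93 went from log2 3.44 (median SE 0.512) to 3.17 (median SE 0.658) with all 93 positive. These genes were picked by their rise in the same data, so this does not decide on scaling as a cause. The 23 chaperones went from a median of log2 3.57 (median SE 0.537) to 2.76 (median SE 0.599) with 23 positive and 10 still called. They were picked by their rise too, so the same limit holds. Scaling and the combined treatment stay open.

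A second pattern was the rise of 24 assembled models in the combined group, 6 of them with a retroelement match. Models with a span of 6 to 7.5 kb made up 12 of the 24 (50%) against 171 of 3343 other tested assembled models (5.12%; Fisher's exact test p = 7.11e-10). That range was set after these spans were seen, so the test cannot tell whether the models are full-length LTR retrotransposons. Transcripts running on from a nearby rising gene explain few, as 2 of 23 loci lay within 10 kb of one, and of 55 tested models with a retroelement match 25 had a positive fold change, with a median of log2 -0.08. Rescaled to equal totals, 12 of the 24 kept their call and the median went from log2 3.51 (median SE 0.477) to 3.87 (median SE 0.682) with all 24 positive. These models were picked by their rise in the same data, so this does not decide on scaling as a cause. Reads shared between copies were not analysed here.

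The third pattern was the interaction of cytosolic ribosomal protein genes, whose median stood log2 1.63 above that of all genes. The lowest value with a library left out was 1.10, against 1 library as the whole cause. Scaling to equal totals left 1.46, but a factor per library nearly cancels here. Genes matched on abundance (20 per ribosomal gene) stood at 0.508. Quantile normalization, which evens the upper ranks, left 0.154, so scaling and abundance stay open. Libraries differed within groups, from 1.88 in combined 3 to 0.08 in combined 2. A response to the combined treatment stays a hypothesis, untested in other animals.

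Other splits of the 6 libraries of each pairwise contrast number 10 with the real one, which is too few for a share under 0.05. The real split gave 11 genes for high temperature against control (highest other 1, 1 split as large), 1 for low oxygen against control (highest other 1, 5 splits as large) and 93 rising with 30 falling genes for combined against control (highest other 1, 1 split as large). It gave 34 for combined against high temperature (highest other 2, 1 split as large), 66 for combined against low oxygen (highest other 3, 1 split as large) and 1 for high temperature against low oxygen (highest other 1, 3 splits as large).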

How the results depend on the processing

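Limma voom and the fit without both combined replicates 1 and 3 were chosen after seeing the data. The others were fixed beforehand, and none was left out. Among named genes, called or not, 4886 values kept direction and side of the threshold under an alternative, 437 lost the call, 66 gained it and 28 turned. The 4886 are thus not all kept calls. Among called lists 1113 values kept the call, 296 lost it and 12 turned. Lists not called are left out. Unless a setting tests fewer genes or leaves fewer libraries, the cause of a change was not tested.

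The number of changed genes at high temperature was 7 with a pseudocount of 0.1, 6 in a fit on its own groups, 205 with library weights (control 2 weighed 5.46, others 0.334 to 1.84) and 7 with voom, and 0 to 16 with a library left out. For low oxygen it was 0 with pseudocounts of 0.1 and 0.5, the filter at FPKM 5, rescaling, the fit on its own groups and voom, 2 without a filter, 3 under quantile normalization and 185 with library weights, and 0 to 4 with a library left out. For the combined group against control it was 74 with a pseudocount of 0.1, 80 without a filter, 30 in the fit on its own groups and 57 with voom, and 50 to 212 with a library left out. Against high temperature it was 22 with a pseudocount of 0.1, 17 when rescaled, 2 in the fit on its own groups, 71 without both combined replicates 1 and 3, and 22 to 67 with a library left out. Against low oxygen it was 28 when rescaled, 22 in the fit on its own groups and 34 to 113 with a library left out. High temperature against low oxygen gave 2 with either pseudocount, 13 with library weights and 0 to 1 with a library left out. The interaction gave 1 with a pseudocount of 0.1, 4 without a filter, 3 with the filter at FPKM 5, 2 when rescaled, 23 with library weights, 0 with voom, 61 without both combined replicates and 2 to 18 with a library left out. The fold threshold, median-of-ratios factors, eBayes without trend and robust eBayes moved none of these counts by over 1.5 times.

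The replicate number was tried as a block: 17 genes at high temperature, 0 at low oxygen and 2 in the interaction. Libraries of the same number correlated at r -0.170 to 0.178 after group means were removed, with a median of 0.0674 against -0.0090 for other pairs and 6 of 18 over 0.1, and 4 of 12 correlated best with their own number. The numbers were therefore not used as pairs.

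With an estimated correlation the number of lists called was 0, 0, 1, 0, 0, 0 and 0 in the order high temperature, low oxygen and combined against control, combined against high temperature and against low oxygen, high temperature against low oxygen, and interaction. With fry it was 5, 0, 7, 0, 5, 0 and 0. Combined against high temperature had 10 lists called, 4 under quantile normalization, 6 in the fit on its own groups and 4 to 11 with a library left out. Combined against low oxygen had 13, and 8 under quantile normalization. The interaction had 7, and 4 to 9 with a library left out. The 1 gene that changed alike at high temperature and low oxygen, and the 1 alike at low oxygen and in the combined group, became 0 with pseudocounts of 0.1 and 0.5, with rescaling and with the replicate block, and 3 under quantile normalization.

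Values that turned sign were mostly small and uncalled. Lactate dehydrogenase A (evm_TU_Chr18_65) turned to log2 0.14 at high temperature with library weights and -0.56 to 0.37 with a library left out (0.16 without control replicate 3, 0.37 without high temperature replicate 3). For high temperature against low oxygen it ranged from -0.56 to 0.37. At low oxygen it was -0.0062 with voom and -0.22 to 0.38 with a library left out. Rescaled, it was -0.21 against control, -0.0034 against high temperature and -0.40 against low oxygen in the combined group, and -0.19 in the interaction. In the combined group against control, VCP was -0.066 and KDM3A -0.19 when rescaled, and KDM3A -0.21 and the VEGF A-A match -0.41 without both combined replicates 1 and 3. Against high temperature, HSP90-beta was -0.41 when rescaled and -0.42 under quantile normalization, hypoxia-inducible factor 1-alpha -0.0156 and -0.0067, and RPS21 -0.076 under quantile normalization. In the interaction, hypoxia-inducible factor 1-alpha was -0.79 when rescaled, -0.69 under quantile normalization and -0.0035 to 0.81 with a library left out, and HSP90-beta was 0.26 without both combined replicates and -0.75 to 0.14 with a library left out.

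Lists whose direction turned in camera had these adjusted p. For combined against control, oxidative phosphorylation had 0.317 when rescaled and 0.0592 under quantile normalization, ubiquitin and proteasome 0.749 when rescaled, and cytosolic ribosomal proteins 0.0148 under quantile normalization. For combined against high temperature, RNA splicing factors had 0.27 when rescaled and 0.635 under quantile normalization, chaperonins 0.846, oxidative phosphorylation 0.485 and cytosolic ribosomal proteins 0.0581 under quantile normalization. In that contrast cilia and flagella had 0.00103 without combined replicate 1 (range 3.51e-06 to 0.436) and ER unfolded protein response 0.745 without combined replicate 3 (range 0.00103 to 0.745). In the interaction, RNA splicing factors had 0.683 when rescaled. In the lists that turned when rescaled the median still lay above that of all genes, as given above.

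Rescaling to equal totals put the median of all genes at log2 -0.77 in the combined group against control, -0.76 against high temperature, -0.88 against low oxygen, -0.15 for high temperature against low oxygen and -0.91 in the interaction. Setting aside the estimated correlation and fry, the lists called in every alternative run for lists numbered 7 at high temperature, 5 at low oxygen, 7 in the combined group, 1, 4 and 8 in the comparisons among treated groups and 1 in the interaction. Without both combined replicates 1 and 3 the lone combined library is assumed to vary like the other groups. Leaving out a library lowered some of the counts above and raised others.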

Other observations

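The tests reported in this part were chosen after the results were seen. Transcripts of a few loci filled much of each library. Major yolk protein models, named for an iron-binding protein stored by echinoderms, took from 4.72% of fragments in control 3 to 26.1% in combined 1. The mitochondrial COX1 locus took from 4.53% in low oxygen 1 to 18.6% in combined 3, and cytosolic ribosomal proteins from 5.35% in low oxygen 1 to 13.025% in combined 3. The ribosomal share lay below the controls in combined 1 and 2.

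Of the 93 genes that rose in the combined group, 9 had no fragment in any control library. Against a floor of 3 fragments over the control group, an unnamed gene on chromosome 21 (11833946 to 11834801) was at least 2943-fold higher, a pair of overlapping assembled models on chromosome 10 (3184174 to 3190996) at least 2190-fold and 625.0-fold, and CG9164 at least 297-fold higher. With these genes at their bound, the median of the rising genes was log2 3.58 instead of 3.44.

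Genes that rose in the combined group lay beside each other more often than random genes. Of the 93, 14 had another within 20 kb, against a median of 0 and a highest value of 8 in random draws. The permutation test over 10000 draws gave p = 1e-04, the smallest these draws can give. The groups included 3 small heat shock genes on chromosome 17 (heat shock protein 67B3, heat shock protein beta-1 and alpha-crystallin A), 3 models on chromosome 9 around the tubulin polyglutamylase TTLL9 and B3GALT1, and CG9164, 260.0 bp from an assembled model. The overlapping pair on chromosome 10 counts as 2 of the 14. Shared control of neighbouring genes may explain part of this, as may reads or transcripts shared between models.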
